A study of Arabidopsis thaliana with 6 samples.

How the data were processed

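Rosettes of Arabidopsis thaliana were profiled on 1-colour Affymetrix microarrays, with 3 arrays of the wild type Col-0 and 3 of the pmr5 mutant. Per the labels' protocols, untreated plants were grown at 22 °C with a 14 h photoperiod and collected at 3 weeks, RNA was extracted with Trizol, and biotinylated cRNA was made from 15 µg of total RNA. The labels call the 3 arrays of each genotype biological replicates. They do not say whether the replicates came from separate sowings or harvests, and no scan date or batch was given in the sources used here.

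The deposited values were log2 signals per probe set, made with RMA in the affy package per the submitters' processing notes, with versions not given in the sources used here. In the deposited log2 values a shared lowest value of 2.19 filled between 25.0% and 26.3% of the probe sets on each array. The step that set this floor is not given in the sources used here. At the floor there is no order between values, and a gene close to it can show only part of a difference. Of the 22746 probe sets tested, 3742 were at the floor on all 6 arrays, 16186 on none, and 4029 had 1 identical value on all 6 arrays. The number of arrays limits the precision of each value.

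The table held 22810 probe sets, of which 64 were Affymetrix controls and were left out of the tests. Gene names came from the platform annotation given with the table. It paired 13513 probe sets with 1 gene and 503 with several genes, and 8730 tested probe sets had no gene in it and stayed unnamed here. Of those with 1 gene, 13436 matched the RefSeq gene table of assembly TAIR10.1, which was used only for names and for the order of neighbouring genes. Locus codes were the only name of 11933 of them, and 1580 had a symbol. No probe set was paired with PMR5, so its transcript and the alternatives planned for it were not analysed here.

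The values were tested without further normalization in R 4.3.3 with limma 3.58.1, as pmr5 minus Col-0, using lmFit and eBayes with the default prior. All tests were 2-sided, and Benjamini-Hochberg adjustment ran over all 22746 probe sets with a threshold of 0.05. A second count required a difference of at least 1 log2 unit, which is 2-fold. Standard errors are those of limma's moderated statistic. Measures of whole arrays were compared by exact permutation, whose smallest p for 3 against 3 arrays is 0.1.

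The model, its threshold, 38 gene lists, the rule for the genes to name and the first set of alternative settings were fixed before the data were examined. The rule named PMR5, then the 12 largest increases and the 12 largest decreases among named genes past the threshold whose groups did not overlap. In each list it then named up to 4 members with the smallest p if at least 1 passed, and otherwise up to 2. Where several probe sets stood for a gene, the list used the one with the highest mean over the 6 arrays. Of the 38 lists, 20 had at least 1 measured member and 8 had the minimum of 3 for a test of the list as a set. The set test was camera with a preset correlation of 0.01, adjusted over the 8 lists, with an estimated correlation beside it. The table's names differed from the list's for 4 members, which stand under their locus codes (AT5G06700, AT1G22690, AT4G34270 and AT2G28390). AT2G31110 entered the TBL list through a synonym.

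The alternative settings of this first set were the replicate number as a block, leaving out each array, a filter on dim probe sets, quantile normalization, centring on array medians, an intensity trend with a robust prior, array weights, Welch's statistic, other thresholds, limma's treat against a 1.2-fold change, all probe sets of a gene, and fry as the set test. Filters on probe sets at the floor or with a mean log2 signal of 6 or less, and fits that took RNA integrity into account, were added after the data were seen. RNA integrity was measured as the mean 3' minus 5' signal difference of the actin, GAPDH and ubiquitin control probe sets.

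The steps were tested on simulated data, in 20 draws over the 22746 probe sets of the comparison of pmr5 with Col-0. In each draw 200 probe sets were changed, all taken from the 16186 above the lowest value on every array. The shares called below do not cover changes in probe sets with an array at that value. The limma fit called 28.6% of the probe sets changed by 1 log2 unit, 54.9% at 2, 71.8% at 3 and 80.9% at 4 log2 units. It called 0.0519% of the unchanged ones. With 200 changed probe sets in a draw the adjustment is less strict than where few differ, so these shares do not hold for a lone change. In the simulation camera, at an unadjusted p under 0.05, called a set of 24 probe sets lowered by 0.5 log2 units in 20 of 20 draws. At the same threshold it called 5% of 400 unchanged sets. These sets held only probe sets above the lowest value on every array, while 4 of the 24 TBL members had identical values on all arrays. The real lists were also held to an adjusted p. The simulated probe sets varied independently, so these shares do not cover lists whose genes are correlated. The lowering was also larger than the mean difference of -0.16 of the TBL list.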

Results

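Transcript levels were measured in untreated rosettes of wild type Col-0 and of the mutant pmr5, isolated for resistance to powdery mildew and known for an altered pectin content of its cell walls. Each genotype had 3 arrays. The median log2 signals of the arrays were 4.68, 4.71 and 4.74 for Col-0 and 4.71, 4.75 and 4.78 for pmr5. Arrays correlated across probe sets at 0.980 to 0.991 within Col-0, 0.985 to 0.995 within pmr5 and 0.981 to 0.993 between the genotypes, with probe sets not being independent replicates. The first principal component held 37.5% of the variance and the second 32.1%, and neither separated the genotypes. The third, with 13.8%, placed every Col-0 array above every pmr5 array (exact permutation p = 0.1, the smallest possible). On the first component Col-0 replicate 1 had a score of 52.3 and the other 5 arrays lay between -30.5 and 12.2. The mean 3' minus 5' difference of the control transcripts, a sign of RNA integrity, was 0.98 ± 0.11 in Col-0 and 0.97 ± 0.13 log2 units in pmr5 (SD, n = 3, exact permutation p = 1). Its highest values were 1.10 in Col-0 replicate 3 and 1.11 in pmr5 replicate 2. The spiked poly-A controls averaged 6.68 ± 0.13 in Col-0 and 6.31 ± 0.24 in pmr5 (SD, n = 3), with every Col-0 array above every pmr5 array (exact permutation p = 0.1, the smallest possible, and 0.55 after adjustment over 11 array measures).

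**Figure D1:**
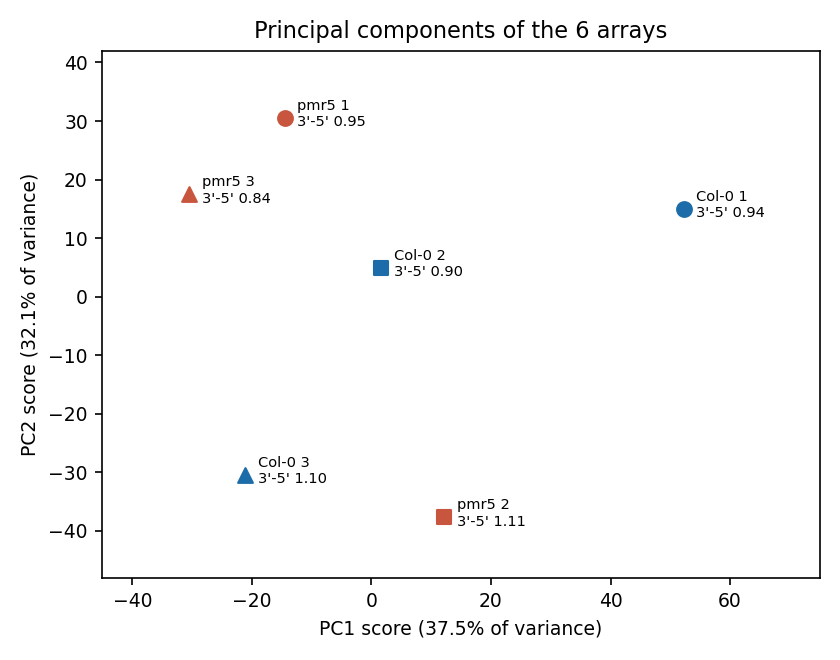
Scores of the 6 arrays on the first and second principal components of the log2 signals, with the percent of variance on each axis and each array's mean 3' minus 5' difference in log2 units beside its point. Col-0 replicate 1 sits apart on the first axis at 52.3, and Col-0 replicate 3 and pmr5 replicate 2 share the low end of the second.

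The comparison of pmr5 with Col-0 asked which transcripts differ in untreated rosettes of the mutant. AT3G27050, singled out after its values were seen, showed the widest gap between the genotypes among named genes whose groups did not overlap. Its log2 signal was 10.63 ± 0.08 in Col-0 and 6.39 ± 0.60 in pmr5 (SD, n = 3), 18.9-fold lower in the mutant, with a log2 difference of -4.24 (SE 0.33). The expansin-like gene EXLA1 was 3.28-fold lower in pmr5, at 7.13 ± 0.35 against 8.85 ± 0.39 (SD, n = 3). The cold-regulated gene COR15A was 2.32-fold lower, and the transcription factor gene WRKY53 was 4.22-fold higher. None of these single differences passed the threshold of the limma test over all probe sets, where the adjusted p was 0.68 for AT3G27050 and 1 for EXLA1, COR15A and WRKY53.

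With limma, 0 probe sets passed an adjusted p under 0.05, and 0 did so with a 2-fold difference. At an unadjusted p under 0.05 there were 591 probe sets, 311 higher and 280 lower in pmr5. A share of 0.05 of the 18717 that varied between arrays would be 936. Probe sets at the lowest value on most arrays can hardly reach such a p, so chance gives fewer than that. Probe sets are not independent, and the other splits of the 6 arrays into 3 and 3 gave from 238 to 1509. The prior of this fit had 0.41 degrees of freedom beside 4 residual ones, so that little variance was shared between probe sets. A statistic with none shared and unequal variances also gave 0 after adjustment, and 298 before it. With 3 arrays per group such a statistic could hardly pass over 22746 tests, so its 0 decides nothing. Among the 15899 varying probe sets above the lowest value on every array, the genotypes did not overlap in 1042, or 6.55%. Chance gives 10% where no values are tied. Some of these probe sets held 1 identical value on most arrays and could not separate in any split, so their chance share is lower. Over all 16186 probe sets above the lowest value the share was 6.44%, and the other splits gave from 3.02% to 14.2%. Leaving out 1 array gave 13 probe sets without pmr5 replicate 2, 4 without pmr5 replicate 3, and 2 each without pmr5 replicate 1 and without Col-0 replicate 3. AT3G27050 was among the 13, with an adjusted p in limma of 0.0381, within a range of 0.0381 to 1 over its 18 alternatives.

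Because no probe set passed the threshold, the genes described next were singled out after their values were seen. Over all tested probe sets 72 were at least 2-fold apart with no overlap between the genotypes, 49 of them higher and 23 lower in pmr5. Of the 10 splits of the arrays into 3 and 3, 6 gave at least 72, the real split included, and the highest gave 260. The count is therefore no sign of a difference between the genotypes. Of the 72 probe sets, 38 had 1 gene name. WRKY22, which encodes a transcription factor of the immune response to microbial patterns, had a log2 difference of 1.74 (SE 0.47), and PUB22, for a U-box ubiquitin ligase, 1.15 (SE 0.31). The lectin gene JAL23 had a difference of 1.92 (SE 0.74), the starch-related gene QQS 2.55 (SE 0.90) and the wax ester synthase gene WSD1 1.60 (SE 0.31). Lower in pmr5 were AT5G47330 at -2.36 (SE 0.71), AT1G57590 at -1.64 (SE 0.46), AT3G44970 at -1.34 (SE 0.18) and TINY2, for a transcription factor, at -1.31 (SE 0.54). The spread within a genotype was wide for several of them, as in QQS with 8.50 ± 1.63 in Col-0 and 11.05 ± 0.14 in pmr5 (SD, n = 3).

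**Figure D2:**
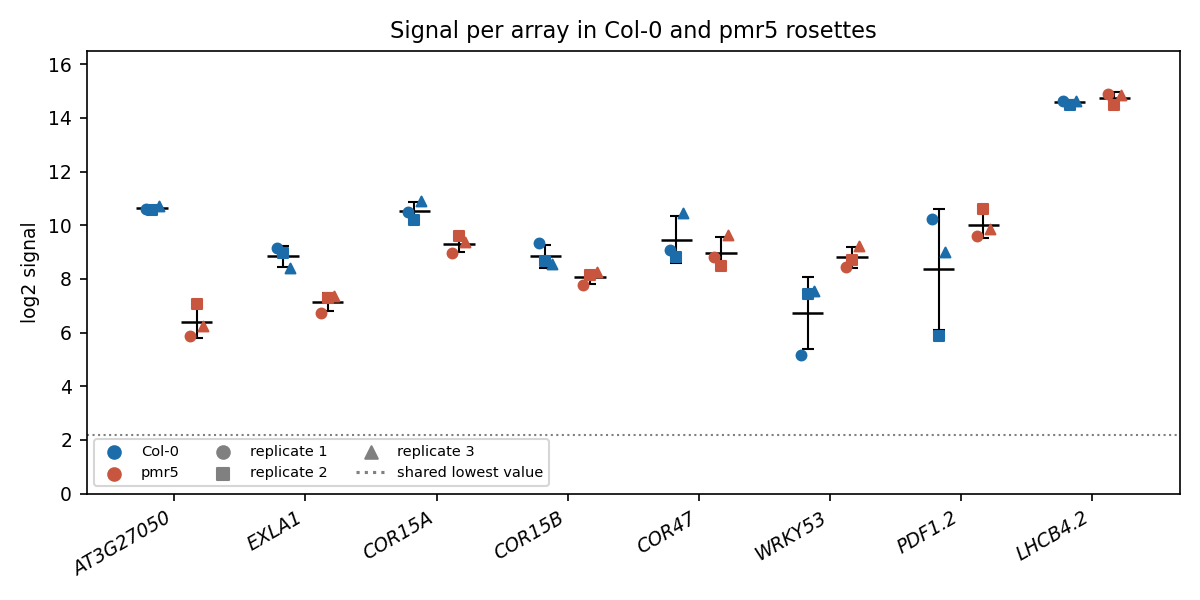
Log2 signal on each of the 6 arrays for 8 genes, with blue points for Col-0, red points for pmr5, a symbol per replicate, and bars for the mean and SD of 3 arrays. AT3G27050 lies near 10.63 in Col-0 and 6.39 in pmr5, and the Col-0 arrays spread widest for PDF1.2.

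PMR5 belongs to the TBL (DUF231) family, whose known members acetylate cell wall polysaccharides. Its 24 measured members had a mean difference of -0.16 ± 0.31 log2 units (SD across genes), and the set test with camera in limma gave an adjusted p of 0.0172 toward lower levels in pmr5. This call was lost, at an adjusted p = 0.267 with an estimated correlation and an adjusted p of 0.26 with fry. The estimated correlation was 0.026, against the preset 0.01, and how much of the loss came from that change was not tested. Of the 24 members, 19 had a signal that varied above the lowest value on every array, and 14 of these were lower and 5 higher in pmr5. AT2G31110 had a difference of -0.40 (SE 0.08) and TBL18 of -0.23 (SE 0.08), both with no overlap between the genotypes. No member passed the test over all genes, and 0 did so adjusted over the list alone. The adjusted p of the set test was 0.117 without Col-0 replicate 1, 0.137 without Col-0 replicate 3 and 0.0695 without pmr5 replicate 1, within a range of 0.00147 to 0.267 over 20 alternatives. The poly-A spikes (-0.37) and the guard cell markers AT1G22690 (0.58) and FMA (0.16) also differed between the genotypes with no overlap.

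**Figure D3:**
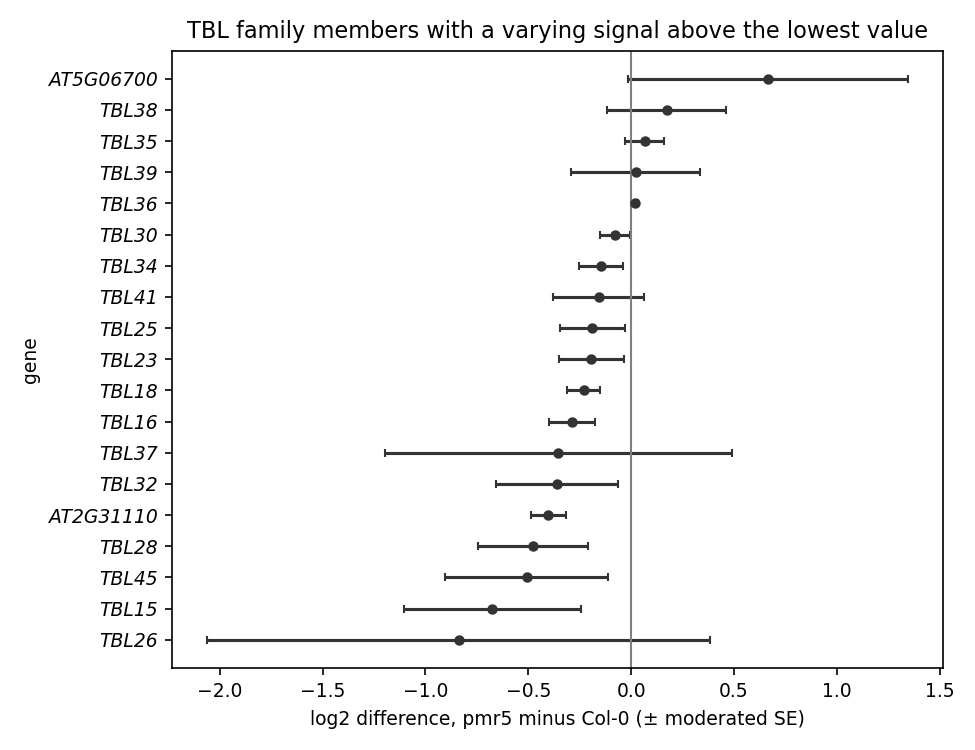
Log2 difference between pmr5 and Col-0 for the 19 TBL family members with a varying signal above the lowest value, with the moderated standard error from limma as the bar. Of the 19 members, 14 lie below 0 and 5 above it.

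Of the 13 loci in the list of abscisic acid, drought and cold genes, only COR15A, COR15B and COR47 were measured, so the list's other members are not covered. These 3 had a mean difference of -0.83, and the set test with camera in limma gave an adjusted p of 0.00259. This call was lost as well, at an adjusted p = 0.267 with an estimated correlation, here 0.158, and an adjusted p of 0.182 with fry. The chloroplast-targeted cold-regulated proteins of COR15A and COR15B are known to stabilize membranes during freezing, and COR47 encodes a dehydrin. COR15A was at 10.52 ± 0.36 in Col-0 and 9.30 ± 0.32 in pmr5 (SD, n = 3), a difference of -1.21 (SE 0.26). COR15B differed by -0.79 (SE 0.27), with no overlap between the genotypes, and COR47 by -0.49 (SE 0.58). For COR47 the Col-0 arrays read 9.08, 8.82 and 10.47 against a pmr5 mean of 8.97, so its difference rests on Col-0 replicate 3. Over all genes 0 members passed, and 1 fell adjusted over the list alone, COR15A at an adjusted p of 0.0231 in limma. Without Col-0 replicate 3 the adjusted p of the set test was 0.0835, within a range of 0.000388 to 0.279 over 20 alternatives. The difference of the poly-A spikes (-0.37) and of the guard cell markers AT1G22690 (0.58) and FMA (0.16) between the same arrays had no overlap either.

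Other cell wall lists did not pass the set test. The 29 measured expansins and xyloglucan endotransglucosylases had a mean difference of -0.04, with 8 lower and 8 higher among the 16 with a varying signal above the lowest value (camera adjusted p = 0.479). The mean was -0.03 without pmr5 replicate 1, -0.10 among probe sets above the median signal and -0.21 among those with a mean log2 signal above 6. EXLA1 at -1.71 (SE 0.29) and EXPA15 at 0.11 (SE 0.04) had the smallest p among them, and 0 members passed adjusted over the list alone. With fry the adjusted p of this list was 0.313 for a shared direction. The mixed form of fry, which asks whether members differ in either direction, gave an adjusted p of 0.0153. The 4 pectin methylesterases and inhibitors had a mean of -0.13 (camera adjusted p = 0.479), with PME61 at -0.41 and PMEPCRF at -0.28. With 1 array left out the list's mean went from -0.36 without Col-0 replicate 1 to -0.01 without Col-0 replicate 3. PME61 went from -0.68 without Col-0 replicate 2 to -0.23 without Col-0 replicate 1, and PMEPCRF from -0.57 without pmr5 replicate 2 to -0.08 without Col-0 replicate 3. GAUT15, for a putative galacturonosyltransferase of pectin synthesis, was at -0.18 (SE 0.16), and COB, which orients cellulose deposition, at -0.31 (SE 0.30). Of the wall-sensing receptor kinase genes, THE1 was at -0.74 (SE 0.28) with no overlap between the genotypes and FER at -0.17 (SE 0.20). Without Col-0 replicate 1 COB was at -0.05, FER at -0.04 and GAUT15 at -0.07. At the other end were COB at -0.57 and GAUT15 at -0.29 without Col-0 replicate 3, and FER at -0.32 without pmr5 replicate 3.

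Defence and stress lists had few measured members. SAG101, of the salicylate defence list, had a difference of 0.14 (SE 0.27), and of -0.14 without Col-0 replicate 1. The defensin gene PDF1.2, a marker of the ethylene and jasmonate response, was at 8.36 ± 2.26 in Col-0 and 10.02 ± 0.51 in pmr5 (SD, n = 3), less than the spread of the Col-0 arrays. In the list of touch and rapid stress genes, WRKY53 differed by 2.08 (SE 0.77), with no overlap between the genotypes, and the zinc finger gene STZ by 0.88 (SE 0.83). Without Col-0 replicate 1, the array apart on the first principal component, the difference of WRKY53 was 1.30. The heat shock gene ATHSP22.0 was at the lowest value on 5 arrays. The anthocyanin genes DFR and UF3GT differed by 0.50 (SE 0.67) and 0.25 (SE 0.86), and the clock gene GI by -0.37 (SE 0.57). Without Col-0 replicate 1 these were -0.13, -0.51 and -0.04, and UF3GT was also at -0.25 without pmr5 replicate 2. At the other end were DFR at 1.03 and UF3GT at 0.68 without Col-0 replicate 2, and GI at -0.85 without pmr5 replicate 2. Without Col-0 replicate 2 the difference of PDF1.2 went from 1.65 to 0.40 and that of STZ to 0.15. In each of these lists 0 members passed over all genes and 0 adjusted over the list alone.

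The photosynthesis list had 7 measured members and a mean difference of 0.04 (camera adjusted p = 0.479), or -0.004 with arrays centred on their medians (camera adjusted p = 0.463). LHCB4.2 differed by 0.17 (SE 0.13) and LHCB4.1 by 0.10 (SE 0.09). With 1 array left out LHCB4.2 went from 0.09 without pmr5 replicate 1 to 0.30 without pmr5 replicate 2, and LHCB4.1 from 0.01 without Col-0 replicate 2 to 0.17 without Col-0 replicate 1. This list passed the set test without pmr5 replicate 2, with a mean of 0.09 and an adjusted p of 0.0266, and with array weights, with a mean of 0.12 and an adjusted p of 0.041, and in none of its other alternatives (adjusted p up to 0.979). Its mean was -0.01 without Col-0 replicate 2 and -0.02 without pmr5 replicate 1. The 12 glutathione transferases had a mean of -0.02 while the direction given by camera was up (adjusted p = 0.899), with GSTU20 at 0.42 (SE 0.14) and no overlap between the genotypes, and GSTU18 at 0.17 (SE 0.09), or 0.09 without pmr5 replicate 3. The mean of this list was 0.03 without pmr5 replicate 1, 0.01 without pmr5 replicate 3 and -0.10 without pmr5 replicate 2. The 7 auxin response genes had a mean of 0.16 and a median of 0, with a median of -0.06 among the 3 with a varying signal (camera adjusted p = 0.883). IAA29 was at 1.28 (SE 0.75) and IAA30 at -0.07 (SE 0.19). With 1 array left out IAA29 went from 0.81 without pmr5 replicate 3 to 2.03 without pmr5 replicate 2, where the list's mean was 0.25, and IAA30 was at 0.11 without Col-0 replicate 3. In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone.

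Markers of other cell types and organs were set beside these groups. Of the guard cell markers, AT1G22690 was at 10.19 ± 0.18 in Col-0 and 10.77 ± 0.10 in pmr5 (SD, n = 3), a difference of 0.58 (SE 0.11), and FMA differed by 0.16 (SE 0.06), both with no overlap between the genotypes. Over all genes 0 of the 2 passed, and 1 rose adjusted over the list alone, AT1G22690 at an adjusted p of 0.00975 in limma. The trichome gene TRY differed by 0.06 (SE 0.85), with values from -0.67 without pmr5 replicate 2 to 0.54 without Col-0 replicate 1. Of 3 root markers, EXPA7 was at the lowest value on all 6 arrays and PYK10 differed by 0.39 (SE 0.87), and the list's mean of 0.13 did not pass the set test (camera adjusted p = 0.883). Without pmr5 replicate 3 PYK10 was at -0.22 and the list at -0.07, without Col-0 replicate 2 at -0.008 and -0.003, and without pmr5 replicate 2 at 1.07 and 0.36. The reference genes AT2G28390 and AT4G34270 differed by -0.09 (SE 0.09) and 0.04 (SE 0.12), the latter by -0.002 with arrays centred on their medians and by -0.03 without Col-0 replicate 2 and -0.04 without pmr5 replicate 2. AT2G28390 was at -0.03 without either of these arrays in turn and at -0.15 without pmr5 replicate 3. For 18 of the 38 lists no member was analysed here. The lists of peroxidases and of TIR-NBS-LRR receptors held no gene, since they were defined by gene descriptions, which were not used here. Among the others were powdery mildew response, jasmonate response, glucosinolate, ribosomal protein, nutrient starvation, flower and vascular genes.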

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

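The filters on the lowest value and on a mean log2 signal above 6, the fits on RNA integrity, and the estimated correlation as a separate alternative were added after the data were seen, although the last was fixed in the design. The count of 0 probe sets ranged from 0 to 13 when 1 array was left out, and the count with a 2-fold difference from 0 to 2, each highest without pmr5 replicate 2. Both were 1 with a mean log2 signal above 6, where AT3G27050 passed at an adjusted p of 0.0393 in limma. Fewer probe sets were tested there, 8879, but its unadjusted p of 0.00012 in the main limma fit would not pass over that many tests either. The filtered fit also estimated its prior anew from the remaining probe sets. Among probe sets above the median signal its adjusted p in limma was 0.0594. The count of 2 lists past the set test became 0 to 3 with 1 array left out. It was 0 without Col-0 replicate 3, 3 without pmr5 replicate 2, and 1 each without Col-0 replicate 1 and pmr5 replicate 1. With array weights it was 1 (photosynthesis, higher in pmr5, in place of both). It was 0 without the 2 arrays of the largest 3' minus 5' difference, 0 with an estimated correlation and 0 with fry for a shared direction. The mean of the TBL list ranged from -0.25 to -0.10 with 1 array left out, and that of the abscisic acid, drought and cold list from -1.03 to -0.65. Where these 2 lists no longer passed, their means were -0.14 and -0.57 with array weights, and -0.23 and -0.63 without the 2 arrays. With an estimated correlation, and with fry, they were -0.16 and -0.83. An estimated correlation widens the test by its construction, and leaving out arrays lowers their number. For array weights and fry the cause was not tested. Apart from these settings and arrays, the alternatives left these 2 lists past the threshold, and no called result changed sign. With the replicate block 0 probe sets passed, 750 before adjustment, and no call of a list changed. The numbers were not taken as a pairing, since the labels do not say that they mark a shared batch. The deviations of same-numbered arrays correlated at 0.12, -0.28 and 0.20, and not every array correlated best with its own number. Deviations from a mean of 3 arrays cancel out, so these correlations cannot exclude a pairing. Of the named genes, AT3G27050 passed in 2 alternatives and no other passed, while differences of uncalled genes changed sign in 19 cases. The alternatives planned for PMR5 were not run. A probe set at the lowest value cannot show a decrease. The 200 probe sets changed per simulated draw were all above the lowest value on every array. The simulated recovery of a change of 2 log2 units was 54.9% in the fit over all probe sets. It was 81.1% with a mean above 6, a fit that also tested fewer probe sets.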

Other observations

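Of the tests here, those on the genes next to AT3G27050, on the lowest value in the TBL list and on the splits for the TBL list were written before their results were seen, and all others were chosen after. Families of genes that share a symbol stem were compared as sets in a further 30 camera tests, none of which passed after adjustment. The 8 measured autophagy genes named ATG had a mean log2 difference of 0.25, with 7 of them higher in pmr5 (adjusted p = 0.0704 in limma, and adjusted p = 0.643 with an estimated correlation). ATG8G was at 5.11 ± 0.30 in Col-0 and 5.58 ± 0.17 in pmr5 (SD, n = 3), and ATG8B differed by 0.28, both with no overlap between the genotypes. The 9 U-box ubiquitin ligase genes named PUB had a mean of 0.38, with 7 higher in pmr5 (adjusted p = 0.0919), among them PUB25 at 0.59 (SE 0.19). Of the 14 sugar transporter genes named SWEET, SWEET4 was at 6.37 ± 0.21 in Col-0 and 5.48 ± 0.22 in pmr5 (SD, n = 3), with no overlap between the genotypes, and the family's adjusted p was 0.383. The 22 genes with a TBL symbol had a mean of -0.19 and did not pass among these families (adjusted p = 0.0919, and adjusted p = 0.643 with an estimated correlation).

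AT3G27050 was 18.9-fold lower in pmr5, with all 3 mutant arrays below all 3 of Col-0. The array medians lay between 4.68 and 4.78, so rescaling whole arrays could move this difference little. The difference nearest to 0 among the deposited, quantile-normalized and median-centred values was -4.23, an outcome near-equal medians fixed in advance. A deletion that reaches the nearest named genes is argued against. The lowest difference among the 3 nearest named genes on each side was -0.60, in AT3G26960, and the nearest of them, AT3G27090, differed by 0.01 with 3 genes in between. A smaller deletion, a sequence variant under the probes carried along with the mutation's background, or an effect of pmr5 itself may each account for the pattern, and these were not tested. On the pmr5 arrays AT3G27050 still read 5.88, 7.05 and 6.23, above the lowest value of 2.19. Whether this remaining signal came from the gene was not tested.

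No probe set passed the threshold, and the first and second principal components did not separate the genotypes. Loss of RNA integrity stays open, because 6 arrays are too few to exclude a relation: the first principal component had r = 0.086 with the 3' minus 5' difference (exact permutation p = 0.896, adjusted 0.896, rho = 0.31 with p = 0.564, over 6 arrays and 2 relations), and r = 0.02 without the 2 arrays farthest from the median. For the second component r was -0.86 (exact permutation p = 0.0431, adjusted 0.0861, rho = -0.60 with p = 0.242) and 0.34 without Col-0 replicate 3 and pmr5 replicate 2, so that the relation rests on those arrays and loss of RNA integrity there may add to the spread. A single array apart stays open as well, since 13 probe sets passed without pmr5 replicate 2. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: all 10 gave at least the 0 probe sets of the real split, as a count of 0 must, with 1 as the highest of the others, and 6 gave at least the real 72 probe sets that were 2-fold apart with no overlap, with 260 as the highest of the others.

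The TBL list was lower in pmr5 by the set test with the preset correlation. The shared lowest value as its source is argued against, since the camera p was 0.000865 without probe sets at that value on any array. A difference in RNA integrity stays open: the mean was -0.15 with the 3' minus 5' difference as a covariate, but that measure was nearly equal between the genotypes, so the covariate could move little, and without the 2 arrays of its largest values the mean was -0.23 and the adjusted p 0.123, within a range of 0.00147 to 0.267 over 20 alternatives. For chance the 10 splits are too few for a share under 0.05, and 2 of them gave a mean as far from 0, with 0.16 for the real split and 0.28 as the highest of the others, between Col-0 replicates 1 and 3 with pmr5 replicate 2 and the rest. Correlation between the family's genes and an effect of the pmr5 genotype may each account for the pattern, and both stay open.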
